A study of Arabidopsis thaliana with 15 samples.

How the data were processed

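Total RNA from 24-day-old Arabidopsis thaliana plants was isolated with an RNeasy Plant Mini kit, labelled with biotin and measured on 15 Affymetrix arrays by the standard protocol, per the labels. The submitters' processing notes name MAS5, without a version. The deposited values are MAS5 signal, an intensity on a linear scale for each of 22810 probe sets, and the mean of the values between the 2nd and the 98th percentile was checked to lie between 499.78 and 499.82 on every array, so the authors' values carry a common scaling. The number of arrays limits the precision. The labels do not say whether replicates came from separate sorts or plants, so that the p-values measure the spread between these samples.

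The arrays fall into 4 populations of sorted cells (CLV3n, CLV3p and FILp with 3 arrays each, WUSp with 2) and a pair of groups for protoplast preparation (Protoplast_induced and Uninduced, 2 arrays each). The groups, comparisons, tests, filters, 23 gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where the text says that a choice came later. Values were used on the log2 scale without further normalization, and 64 control probe sets were set aside. A probe set was tested if it lay above its array's 40th percentile on at least 2 arrays of the fit, which left 15052 probe sets in the fit of the 11 arrays of sorted cells and 13911 in the fit of the 4 arrays of the protoplasting pair. Group means were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with trend and robust), two-sided, with Benjamini-Hochberg adjustment over the tested probe sets of each comparison and a threshold of 0.05. Signals given for a group are geometric means over its arrays. Many low signals are near background. Where it moved a gene by over 0.1, the text adds the log2 difference, called floored, with every signal under the 20th percentile of all values of the arrays in the fit raised to it. This floor was a signal of 19.5 in the fit of sorted cells and 19.2 in that of the protoplasting pair. Simulated data took the spread of each probe set from these arrays, as normal noise independent between probe sets and equal across groups, with 200 probe sets changed. On them the tests recovered 60%, 61%, 33%, 46% and 91% of 2-fold changes and 85%, 93%, 88%, 84% and 99% of 4-fold changes for CLV3p against CLV3n, CLV3p against FILp, CLV3p against WUSp, WUSp against FILp and the protoplasting pair. In 20 further draws a mean of 5.41%, 5.87%, 5.69%, 6.17% and 9.69% of the calls were false, so that in the simulation the threshold of 0.05 was exceeded most for the protoplasting pair. The real comparisons had far more calls, which makes the adjusted threshold less strict, so neither kind of share carries over to them.

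Genes were named only from the probe table supplied with the values, which pairs 13513 probe sets with 1 gene and 503 with several. It gives no gene for 8730 other probe sets, so only 53 of the 404 genes of the lists fixed in advance have a probe set of their own, and WUS, FIL, STM and CLV1 have none. Probe sets without a single gene count in the totals and are not named. After that table was read and before any fold change was computed, 26 further lists were written from the genes it covers. Where a gene has several probe sets, the one with the highest mean represents it. Lists with at least 5 tested members were tested with camera (limma) at a preset correlation of 0.01, adjusted over all lists and comparisons, and again with a correlation estimated from the arrays. Smaller lists are described only. Genes named per comparison are the gene CLV3, those with the largest fold changes among calls whose arrays do not overlap, up to 4 called members per list with the largest changes, and for each population the genes with the largest smaller one of its fold changes over the other populations, in order of size. The text names fewer of these, in order of measured fold, and for genes with signals under the floor that order is not a ranking of the true changes. The checks in the closing section cover all of them.

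The overlap of protoplasting calls with cell type calls used Fisher's exact test (two-sided) on the 13582 probe sets tested in both fits. The counts of probe sets higher in 1 population than in both others are set beside the product expected under independence and beside simulations with 50 draws. Alternatives fixed in advance were quantile normalization, centring each array on its median, the floor, no filter, a filter at the 60th percentile, plain eBayes, array weights, a single fit of all 15 arrays, the replicate number as a block, only the groups compared, removal of probe sets called in protoplasting, and leaving out each array in turn. Chosen after seeing the data were a block for the hybridisation batch read from the bioC controls, fits within each batch, a fit without the pair of arrays with the highest actin 3'/5' ratio, a centred version of the list tests, and the list tests with each array left out in turn. Figures were drawn with matplotlib 3.10.9. Genome coordinates were not used here.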

Results

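The series profiled cells of the shoot apex of Arabidopsis that carry the names of meristem genes, and 15 arrays were compared. CLV3 encodes a peptide signal of the stem cells, WUS a homeodomain transcription factor of the cells that maintain them, and FIL a YABBY transcription factor of the outer side of young organs. CLV3p, CLV3n and FILp have 3 arrays each and WUSp has 2, and the design text states that the CLV3p cell type is absent from CLV3n. Protoplast_induced and Uninduced, with 2 arrays each, are read here as material after and without protoplast preparation. Median signals ran from 156 to 199.9. Spearman correlations across probe sets, which are not independent replicates, lay between 0.952 and 0.982 for the 12 pairs of arrays within a group and between 0.920 and 0.957 for the 45 pairs from different sorted populations. The first 3 principal components held 41.5%, 15.6% and 12.3% of the variance.

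The hybridisation control bioC divided the arrays. Its signal was 281 to 349 on CLV3n 3, CLV3p 3 and the 3 FILp arrays, the low bioC batch, and 745 to 1203 on the others, the high bioC batch. The hybridisation controls bioB and cre did not divide the arrays in this way. In the low batch bioB had log2 signals of 7.95 to 8.36 and cre of 13.50 to 13.92. In the high batch they had 7.97 to 8.54 and 13.08 to 14.07, so the batches rest on bioC alone. FILp and WUSp share no batch, and they are tied only through CLV3p and CLV3n. The actin 3'/5' ratio, a sign of RNA degradation or short labelled products, was highest on CLV3n 1 and CLV3p 1 (log2 4.203 and 3.78), while the other sorted arrays had 2.14 to 2.98. The ubiquitin 3'/5' ratio was lowest on WUSp 1 and WUSp 2 (log2 0.74 and 1.04, against 1.305 to 2.41 on the other sorted arrays). These arrays were also the lowest of the sorted ones in the poly-A spike controls (log2 8.84 and 8.59, against 9.17 to 10.86) and in the 25S ribosomal RNA control (signals of 18502.5 and 18406, against 23685 to 36195). These controls coincide with the group, and no fit here separates them from a difference of the WUSp cells.

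CLV3p was compared with CLV3n to find what marks the CLV3p cells against cells without them. The mean signal of CLV3 was 876 in CLV3p and 9.13 in CLV3n, a log2 difference of 6.58 ± 0.64 (SE, n = 3 and 3; adjusted p = 3.65e-06; 5.49 floored). It was 6.29 within the high and 7.17 within the low bioC batch. YAB5 and YAB3, YABBY genes like FIL, were lower in CLV3p, with log2 differences of -4.56 ± 0.65 (adjusted p = 0.000177; -2.88 floored) and -2.28 ± 0.41 (adjusted p = 0.0013), and the boundary genes PTL and LAS had -4.44 ± 0.40 (adjusted p = 1.43e-06; -3.81 floored) and -1.22 ± 0.29 (adjusted p = 0.0105). ULT1 and POL, regulators of meristem size, were 1.84-fold and 1.52-fold higher (adjusted p = 0.027 and 0.0286).

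In the list of 9 nuclear photosynthesis genes, 7 were lower in CLV3p and none higher, and all 9 were lower when adjusted over the list alone. Its median was -1.09 (-1.06 within the high and -1.38 within the low bioC batch, and -1.002 without CLV3n 1 and CLV3p 1), and its adjusted p was 8.17e-08 by camera, but adjusted p = 0.216 with an estimated correlation. PRK, the phosphoribulokinase of the Calvin cycle, fell by 1.72 ± 0.25 on the log2 scale relative to CLV3n, and the antenna protein gene LHCB4.1 by 1.70 ± 0.21. The added list of 27 nuclear genes for chloroplast proteins, which shares the theme, had 11 lower and a median of -0.87, with PORB at -1.84 ± 0.25 (camera adjusted p = 1.41e-09, and adjusted p = 0.216 with an estimated correlation). Of 12 auxin genes in the added list, 8 were lower and 1 was higher, with a median of -1.61 (adjusted p = 1.68e-06, and adjusted p = 0.216 with an estimated correlation). The conjugating enzyme genes GH3.3 and GH3.17 had -5.46 ± 0.39 and -3.36 ± 0.55 (-2.78 floored), and the kinase gene PID2 had -3.33 ± 0.76 (-1.67 floored). The auxin list fixed in advance shares genes such as IAA20 and YUC4 with the added list, so the 2 lists are not separate evidence. Its 4 measured members split into 3 lower and 1 higher. The auxin response repressors IAA20, IAA30 and IAA29 had -3.27 ± 0.48 (-2.64 floored), -2.47 ± 0.38 and -1.75 ± 0.43. YUC4, an enzyme of auxin synthesis, went the other way at 0.75 ± 0.22 (adjusted p = 0.0315). The added lateral organ list had 7 of 15 lower and 2 higher (9 and 3 when adjusted over the list alone), with a median of -1.05, and ROXY1 and PUCHI had -3.55 ± 0.27 and -2.92 ± 0.35 (list adjusted p = 0.00593, and adjusted p = 0.216 with an estimated correlation).

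Of 17 DNA repair genes in the added list, 6 were higher in CLV3p and none lower, with a median of 0.53 (0.60 and 0.51 within the high and low bioC batch; adjusted p = 0.000495, and adjusted p = 0.216 with an estimated correlation). The uracil DNA glycosylase gene UNG and EME1A, which encodes a nuclease subunit, had 1.34 ± 0.22 and 1.01 ± 0.22. Of 15 chromatin genes, 5 were higher, with a median of 0.24, and the remodeller gene CHR40 had 1.27 ± 0.15 (list adjusted p = 0.00773, and adjusted p = 0.216 with an estimated correlation). PHV, a homeodomain gene of the upper organ side and the only measured member of its list, was 1.72-fold higher (adjusted p = 0.00253). It was not called for CLV3p against FILp or WUSp, with log2 differences of -0.05 and 0.12. The cytokinin response gene ARR15 was 2.38-fold higher than in CLV3n (adjusted p = 0.0378). Of 11 expansin and xyloglucan endotransglucosylase genes, 4 were lower, with a median of -0.59, among them EXPA4 (-2.13 ± 0.36) and XTH32 (-2.03 ± 0.33; list adjusted p = 0.00759, and adjusted p = 0.216 with an estimated correlation). Ribosomal protein genes had 3 of 101 lower (0 when adjusted over the list alone) and a median of -0.17 (adjusted p = 0.000911, and adjusted p = 0.528 with an estimated correlation), and this median was -0.00128 when each array was centred on its median, with the list still called (adjusted p = 0.0361). Genes chosen by measured fold as higher in CLV3p include AT3G25610 (4.18 ± 1.04; 3.03 floored), AT1G26680 (4.14 ± 0.63) and the glycosyltransferase gene UGT73B4 (3.43 ± 1.01; 1.72 floored). Those chosen as lower include AT1G28400, AT4G23670, AT4G09890 and AT1G29270, with -6.63 ± 0.95, -6.53 ± 0.72, -6.39 ± 0.75 and -6.35 ± 0.51. Their signals in CLV3p were 1.33 to 2.94, under the floor of 19.5, and floored they had -3.66, -3.80, -2.52 and -3.54.

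In all, 2082 of 15052 probe sets differed, 735 higher and 1347 lower in CLV3p, of which 221 and 1002 by at least 2-fold. With each array centred on its median, which moved the median of all probe sets by 0.17, 2715 differed and the share higher rose from 35.3% to 59.8%. The count was 2570 with the bioC batch as a block, 1134 within the high batch, 1184 within the low batch (1 array per group) and 1651 without CLV3n 1 and CLV3p 1. Leaving out 1 array left as few as 2 of the 6 DNA repair genes higher (without CLV3n 2 or CLV3p 3), 2 of the 5 chromatin genes higher and 0 of the 3 ribosomal protein genes lower (both without CLV3p 3). Without both CLV3n 1 and CLV3p 1 the calls of ULT1, POL, YUC4, ARR15, IAA29, PID2, AT3G25610 and UGT73B4 ended (adjusted p = 0.102, 0.0646, 0.0648, 0.133, 0.083, 0.0571, 0.0523 and 0.087), and UGT73B4 fell short when floored (adjusted p = 0.0516). Calls also ended without CLV3n 1 for ULT1, POL, YUC4, ARR15 and IAA29 (adjusted p = 0.112, 0.0574, 0.0727, 0.142 and 0.0574), without CLV3n 2 for LAS, YUC4, IAA29 and UGT73B4 (0.0525, 0.125, 0.0603 and 0.0877) and without CLV3n 3 for POL (0.0806). They ended without CLV3p 1 for AT3G25610 and UGT73B4 (0.0611 and 0.102), without CLV3p 2 for POL, YUC4 and ARR15 (0.0584, 0.148 and 0.105) and without CLV3p 3 for ULT1, POL, ARR15, AT3G25610 and UGT73B4 (0.123, 0.0991, 0.112, 0.068 and 0.168).

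**Figure D1:**
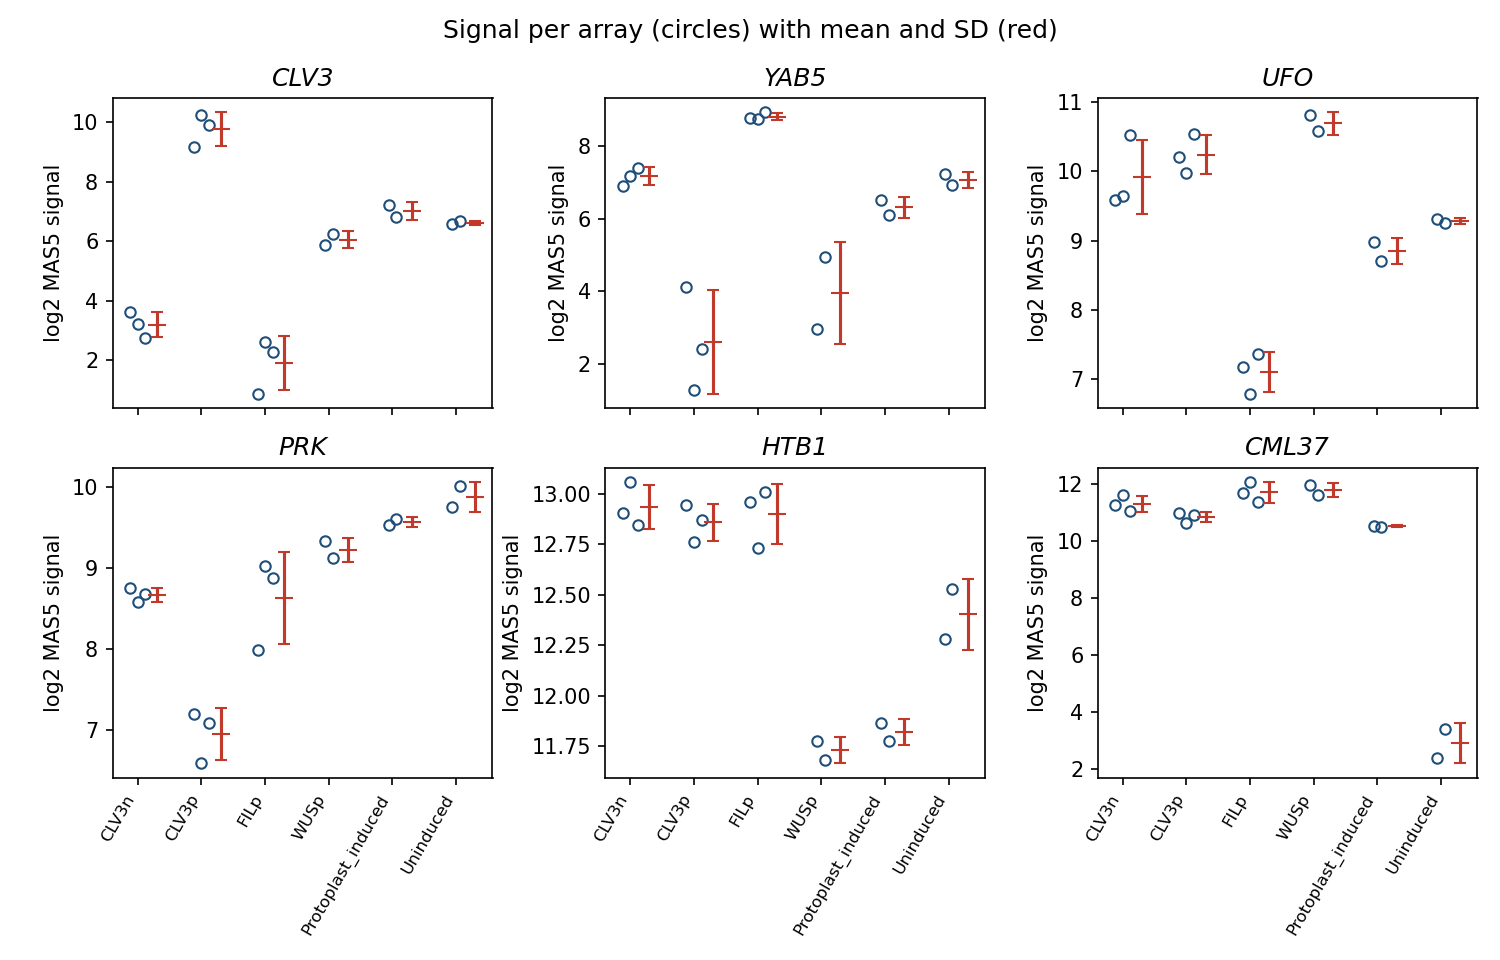
Signal of 6 genes on each of the 15 arrays (vertical axis, log2 MAS5 signal; horizontal axis, the 6 groups). Circles are arrays, and the red bar gives the mean and SD of the group. CLV3 has a mean of 9.77 in CLV3p and 1.91 in FILp, and CML37 has 2.90 in Uninduced and at least 10.53 in each other group.

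CLV3p and FILp, 2 of the named populations, were compared next. CLV3 had signals of 876 and 3.75 in them, a log2 difference of 7.87 ± 0.64 (n = 3 and 3; adjusted p = 2.99e-07; 5.49 floored; 8.01 within the low bioC batch). For this comparison the values within the low batch rest on CLV3p 3 as the only CLV3p array. All FILp arrays lie in that batch, so the values with the batch block are not a separate check. YAB5 and YAB3 were lower in CLV3p, at -6.21 ± 0.65 (-4.53 floored) and -3.53 ± 0.41, and PTL at -4.67 ± 0.40 (-4.04 floored). Both measured regulators of meristem size were higher, POL by 1.04 ± 0.17 and ULT1 by 0.95 ± 0.25, and ARR15 was higher by 1.70 ± 0.38.

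Photosynthesis genes were again lower in CLV3p, 7 of 9 over all probe sets and 9 when adjusted over the list alone, with a median of -1.06 (-1.24 with the bioC batch block, -1.26 within the low batch; adjusted p = 6.8e-06, and adjusted p = 0.233 with an estimated correlation). PRK had -1.68 ± 0.25 and LHCB4.1 -1.67 ± 0.21. Of the 27 added genes for chloroplast proteins, 15 were lower and 1 higher, with a median of -0.73 and PORB at -2.84 ± 0.25 (list adjusted p = 8.65e-07, and adjusted p = 0.283 with an estimated correlation). Auxin genes had 9 of 12 lower and 1 higher, with a median of -2.005 (-2.13 with the block, -2.19 within the low batch; adjusted p = 2.59e-05, and adjusted p = 0.216 with an estimated correlation), including GH3.3 (-5.84 ± 0.39), IAA20 (-4.19 ± 0.48; -3.57 floored) and GH3.17 (-4.08 ± 0.55; -3.51 floored). The exception was YUC4, at 3.07 ± 0.22. The lateral organ list had 6 of 15 lower and 2 higher, a median of -0.44 and a mean of -1.25, with ROXY1 at -5.20 ± 0.27 (list adjusted p = 0.014, and adjusted p = 0.216 with an estimated correlation). DNA repair genes had 4 of 17 higher, with a median of 0.41 (0.56 with the block, 0.58 within the low batch), UNG at 1.74 ± 0.22 and FANCM at 1.05 ± 0.23 (list adjusted p = 0.0132, and adjusted p = 0.325 with an estimated correlation). Chromatin genes had 5 of 15 higher and a median of 0.45, with CHR40 at 1.77 ± 0.15 and CHR18 at 1.32 ± 0.25 (list adjusted p = 0.0306, and adjusted p = 0.288 with an estimated correlation).

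Plastid-encoded transcripts had 10 of 59 higher in CLV3p and 1 lower, with a median of 0.48, led by rps4 (2.84 ± 0.21) and rpoC2 (1.88 ± 0.29). Their list was called with an adjusted p of 0.0012, but adjusted p = 0.608 with an estimated correlation, and the call ended with the bioC batch block (median 0.22, 0.18 within the low batch; adjusted p = 0.184). Of 101 ribosomal protein genes, 1 was higher and 10 were lower (6 when adjusted over the list alone), with a median of -0.13 (adjusted p = 0.0456, and adjusted p = 0.711 with an estimated correlation), and the list passed no longer with each array centred on its median (adjusted p = 0.15). Genes chosen by measured fold as higher in CLV3p include AT1G26680 (7.60 ± 0.63; 6.20 floored), AT1G65810 (7.27 ± 0.93; 6.44 floored) and AT2G16890 (5.27 ± 0.62; 4.93 floored). Those chosen as lower include AT1G23960 (-7.17 ± 0.46; -6.49 floored), AT1G29270 (-7.04 ± 0.51; -4.23 floored), AT1G62500 (-6.89 ± 0.19) and AT5G44630 (-6.63 ± 0.23). A total of 3407 probe sets differed, 1575 higher and 1832 lower in CLV3p, and 665 and 1130 of them by at least 2-fold. With each array centred on its median 3524 differed, and the share higher was 55.3% in place of 46.2%. The count was 2926 with the bioC batch as a block. Leaving out 1 array left as few as 4 of the 10 plastid-encoded transcripts higher (without CLV3p 1 or FILp 2) and 3 of the 10 ribosomal protein genes lower (without FILp 1). List calls ended without CLV3p 3 for chromatin, DNA repair and ribosomal protein genes (adjusted p = 0.108, 0.059 and 0.234), without CLV3p 1 for plastid-encoded transcripts (0.0612), without FILp 1 for chromatin and ribosomal protein genes (0.0531 and 0.181) and without FILp 3 for ribosomal protein genes (0.266). ULT1 lost its call without CLV3p 3 (adjusted p = 0.0505).

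CLV3p and WUSp were compared with 3 and 2 arrays. CLV3 was higher in CLV3p, with signals of 876 and 66.4 and a log2 difference of 3.72 ± 0.72 (adjusted p = 0.00161; 3.79 with the bioC batch block and 3.65 within the high batch). CR4, a receptor kinase gene of the epidermis, was 3.75-fold higher (1.91 ± 0.19), and YUC4 was 4.89-fold higher (2.29 ± 0.24). All 5 measured core histone genes were higher in CLV3p, with a median of 0.96 (1.09 with the block, 1.13 within the high batch), HTB2 at 1.28 ± 0.19 and HTB1 at 1.13 ± 0.15 (list adjusted p = 0.000719, and adjusted p = 0.216 with an estimated correlation). Ribosomal protein genes had 43 of 101 higher and none lower, with a median of 0.47 (0.47 with the block, 0.51 within the high batch; adjusted p = 6.6e-10, and adjusted p = 0.273 with an estimated correlation), for example AT1G23410 (1.42 ± 0.33) and AT1G15250 (1.39 ± 0.24). Of the 4 ribosomal protein genes fixed in advance, 2 were higher, and 3 when adjusted over the list alone. The bioC block does not remove the differences of the WUSp arrays in the ubiquitin ratio, the poly-A spikes and the 25S control.

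Photosynthesis genes had 7 of 9 lower in CLV3p, and 8 when adjusted over the list alone, with a median of -1.29 (-1.07 with the block, -1.14 within the high batch; adjusted p = 7.66e-07, and adjusted p = 0.216 with an estimated correlation). PRK had -2.27 ± 0.28 and RCA, which encodes Rubisco activase, -1.96 ± 0.20. The 27 genes for chloroplast proteins had 13 lower and 1 higher, with a median of -0.65 and PORB at -2.35 ± 0.28 (list adjusted p = 3.02e-06, and adjusted p = 0.288 with an estimated correlation). DNA repair genes had 4 of 17 higher and a median of 0.62, with UNG at 1.301 ± 0.24 and ATNTH1 at 0.87 ± 0.19 (list adjusted p = 0.014, and adjusted p = 0.325 with an estimated correlation), and the list call ended with the bioC batch block (median 0.49, 0.51 within the high batch; adjusted p = 0.0538). CHR40 had 1.28 ± 0.17, while its list had 4 of 15 higher and 1 lower (adjusted p = 0.13). The expansin and xyloglucan endotransglucosylase genes had 4 of 11 lower and 1 higher, with a median of -0.45, XTH32 at -2.56 ± 0.37 and XTH18 at -2.23 ± 0.29 (list adjusted p = 0.0219, and adjusted p = 0.216 with an estimated correlation). Calcium and wound response genes had 5 of 13 lower and a median of -0.62, with WRKY6 at -2.25 ± 0.60 (-1.99 floored), the ubiquitin ligase gene PUB23 at -1.78 ± 0.34 and WRKY53 at -1.52 ± 0.47 (list adjusted p = 0.0295, and adjusted p = 0.627 with an estimated correlation), and with the bioC batch block the median was -0.38 (adjusted p = 0.184). Plastid-encoded transcripts had 3 of 59 higher and 7 lower, with a median of -0.31 (adjusted p = 0.0392, and adjusted p = 0.729 with an estimated correlation), or -0.16 with the block (adjusted p = 0.275).

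The auxin genes had 4 of 12 lower and 2 higher and were not called (adjusted p = 0.289), although GH3.3 was lower at -3.38 ± 0.44. Both measured meristem size regulators were higher, ULT1 by 0.96 ± 0.27 and POL by 0.57 ± 0.19, and PTL was lower (-1.60 ± 0.45; -0.98 floored, adjusted p = 0.0508). SHI, a gene of organ development, was 5.72-fold higher. Genes chosen by measured fold as higher in CLV3p include AT5G26280 (7.34 ± 0.77; 3.19 floored), AT1G65810 (6.97 ± 1.04; 6.66 floored), the transcription factor genes SHN3 (5.66 ± 0.43; 4.70 floored) and ATMYC1 (4.99 ± 0.34; 4.76 floored), and those chosen as lower include AT1G23960 (-7.46 ± 0.52; -6.78 floored), the methionine lyase gene MGL (-6.91 ± 1.25; -4.73 floored), AT4G09760 (-6.73 ± 0.53) and AT1G49750 (-6.09 ± 0.82; -4.84 floored). A total of 3616 probe sets differed, 1755 higher and 1861 lower in CLV3p, and 804 and 1173 of them by at least 2-fold. Centred, 3586 differed, and the share higher was 51.9% in place of 48.5%. The count was 4245 with the bioC batch as a block, 3175 within the high batch, 1630 without WUSp 1 and 2091 without WUSp 2. Without WUSp 1 and without WUSp 2, 8 and 21 of the 43 ribosomal protein genes were still higher, 2 and 3 of the 5 histone genes, and 2 and 2 of the 4 DNA repair genes, and 0 of the 2 ribosomal protein genes fixed in advance in either case. Without WUSp 1, 1 of the 5 calcium and wound genes and 3 of the 7 plastid-encoded transcripts were still lower, and 1 of the 4 chromatin genes was still higher. List calls ended without WUSp 1 for calcium and wound genes and plastid-encoded transcripts (adjusted p = 0.207 and 0.479), without CLV3p 2 for plastid-encoded transcripts (0.191) and without CLV3p 3 for calcium and wound genes, DNA repair genes and plastid-encoded transcripts (0.124, 0.0642 and 0.257). Without WUSp 1 the calls of ULT1, POL, WRKY6, WRKY53 and AT1G23410 ended (adjusted p = 0.272, 0.171, 0.119, 0.323 and 0.0614), and without WUSp 2 those of PTL, POL and WRKY6 (adjusted p = 0.207, 0.173 and 0.0627). POL also fell short without CLV3p 1 (0.0558), POL and WRKY53 without CLV3p 2 (0.0719 and 0.0697) and ULT1, POL and WRKY53 without CLV3p 3 (0.0648, 0.0958 and 0.087), and POL without both CLV3n 1 and CLV3p 1 (0.053).

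WUSp and FILp share no bioC batch, so that the comparison rests on arrays whose group and batch coincide, and the values with a batch block use CLV3p and CLV3n as the bridge. CLV3 was higher in WUSp than in FILp, with signals of 66.4 and 3.75 (4.15 ± 0.72, n = 2 and 3; adjusted p = 0.000966; 1.77 floored; 3.93 with the block). YAB5, YAB3 and PTL were lower in WUSp, at -4.85 ± 0.73 (-4.19 floored), -3.57 ± 0.46 and -3.06 ± 0.45, and so was CR4 (-1.73 ± 0.19). UFO, an F-box gene of floral meristems, was 11.96-fold higher in WUSp (3.58 ± 0.27; 4.26 with the block). ARR15 was higher by 1.57 ± 0.42 (adjusted p = 0.0195).

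Ribosomal protein genes had 46 of 101 lower in WUSp and none higher, with a median of -0.55 (-0.64 with the block; adjusted p = 2.14e-20, and adjusted p = 0.216 with an estimated correlation). AT1G23410 had -1.77 ± 0.33 and AT5G59240 -1.40 ± 0.26. The 4 ribosomal protein genes fixed in advance had 2 lower, and all 4 when adjusted over the list alone. Here too the ubiquitin ratio, the poly-A spikes and the 25S control differ between the groups. Core histone genes had 4 of 5 lower, with a median of -0.73 (-1.12 with the block), AT2G28720 at -1.23 ± 0.26 and HTB1 at -1.17 ± 0.15 (list adjusted p = 0.000495, and adjusted p = 0.216 with an estimated correlation). Auxin genes had 6 of 12 lower and 2 higher, with a median of -1.14 (-1.63 with the block; adjusted p = 0.00197, and adjusted p = 0.216 with an estimated correlation), among them the kinase gene WAG2 (-4.20 ± 0.29), IAA20 (-2.89 ± 0.54), GH3.17 (-2.64 ± 0.62) and GH3.3 (-2.46 ± 0.44). The lateral organ list had 7 of 15 lower and 2 higher, with a median of -1.49 (-1.70 with the block), and ROXY1 at -4.30 ± 0.31 (list adjusted p = 0.00364, and adjusted p = 0.216 with an estimated correlation). Photosynthesis genes were not called between these populations (1 of 9 higher, adjusted p = 0.183), with RCA at 0.90 ± 0.20, and neither were the genes for chloroplast proteins (adjusted p = 0.847) nor the DNA repair genes (adjusted p = 0.968).

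Plastid-encoded transcripts had 11 of 59 higher in WUSp and none lower (19 and 1 when adjusted over the list alone), with a median of 0.87 (0.39 with the block, adjusted p = 0.012), ndhD at 1.82 ± 0.53 and cemA at 1.59 ± 0.36 (list adjusted p = 2.6e-10, and adjusted p = 0.288 with an estimated correlation). Wound response genes had 3 of 13 higher and none lower (4 and 1 when adjusted over the list alone) and a median of 0.54, with WRKY53 at 1.63 ± 0.47 (list adjusted p = 0.0222, and adjusted p = 0.627 with an estimated correlation). With the batch block that median was -0.18 and the list was no longer called (adjusted p = 0.961). Chaperone genes had 3 of 15 higher and a median of 0.20 (adjusted p = 0.0431, and adjusted p = 0.302 with an estimated correlation), and the call ended with the block (adjusted p = 0.272) and with quantile normalization (adjusted p = 0.0669). Both measured genes of the cell wall list, XTH19 and XTH18, were higher (3.31 ± 0.98, 2.31 floored, and 2.08 ± 0.29). AT1G26680, AT3G15650, AT3G19370 and AT5G50010 were chosen by measured fold as higher in WUSp, at 7.38 ± 0.70 (5.98 floored), 6.68 ± 0.25, 5.405 ± 1.11 (2.34 floored) and 5.20 ± 0.66 (4.48 floored). AT5G26280, AT1G73620, AT5G55330 and AT5G45960 were chosen as lower, at -5.15 ± 0.77, -4.99 ± 0.68, -4.97 ± 0.40 and -4.86 ± 0.45, with WUSp signals of 1.0995, 5.17, 5.51 and 9.78. Floored, they had -1.002 (adjusted p = 0.212), -3.08, -3.15 and -3.87, so that AT5G26280 lost its call.

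A total of 2253 probe sets differed, 1096 higher and 1157 lower in WUSp, and 656 and 685 of them by at least 2-fold. Centred, 2197 differed, and the share higher was 54.3% in place of 48.6%. The count was 1872 with the batch block (798 higher and 1074 lower), 980 without WUSp 1, 1247 without WUSp 2 and 1415 without FILp 3. Without WUSp 1, 10 of the 46 ribosomal protein genes and 2 of the 4 histone genes were still lower, and 2 of the 11 plastid-encoded transcripts and 0 of the 3 wound response genes still higher. Of the ribosomal protein genes 20 were lower without WUSp 2, 20 without FILp 1 and 17 without FILp 3, and in each of these fits and without WUSp 1 none of the 2 fixed in advance. Histone genes had 2 lower without FILp 1 or FILp 3 too. The calcium and wound list was not called without FILp 3 or WUSp 1 (adjusted p = 0.102 and 0.228), nor the chaperone list without FILp 2, FILp 3, WUSp 1 or WUSp 2 (0.0579, 0.102, 0.057 and 0.0614). The block ended the calls of XTH19, RCA, WRKY53, ndhD and cemA (adjusted p = 0.184, 0.0991, 0.42, 0.468 and 0.182), and XTH19 also fell short without CLV3n 1 and CLV3p 1 (0.078). Leaving out WUSp 1 ended those of XTH19, RCA, WRKY53, ndhD, cemA, AT3G19370 and AT5G59240 (adjusted p = 0.218, 0.0547, 0.326, 0.244, 0.112, 0.0566 and 0.0587). Leaving out WUSp 2 ended those of ARR15, XTH19, GH3.17, ndhD and AT3G19370 (adjusted p = 0.338, 0.111, 0.1003, 0.117 and 0.0636). ARR15, WRKY53 and ndhD also fell short without FILp 1 (0.064, 0.111 and 0.073), ndhD without FILp 2 (0.0702) and WRKY53 and ndhD without FILp 3 (0.114 and 0.142).

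**Figure D2:**
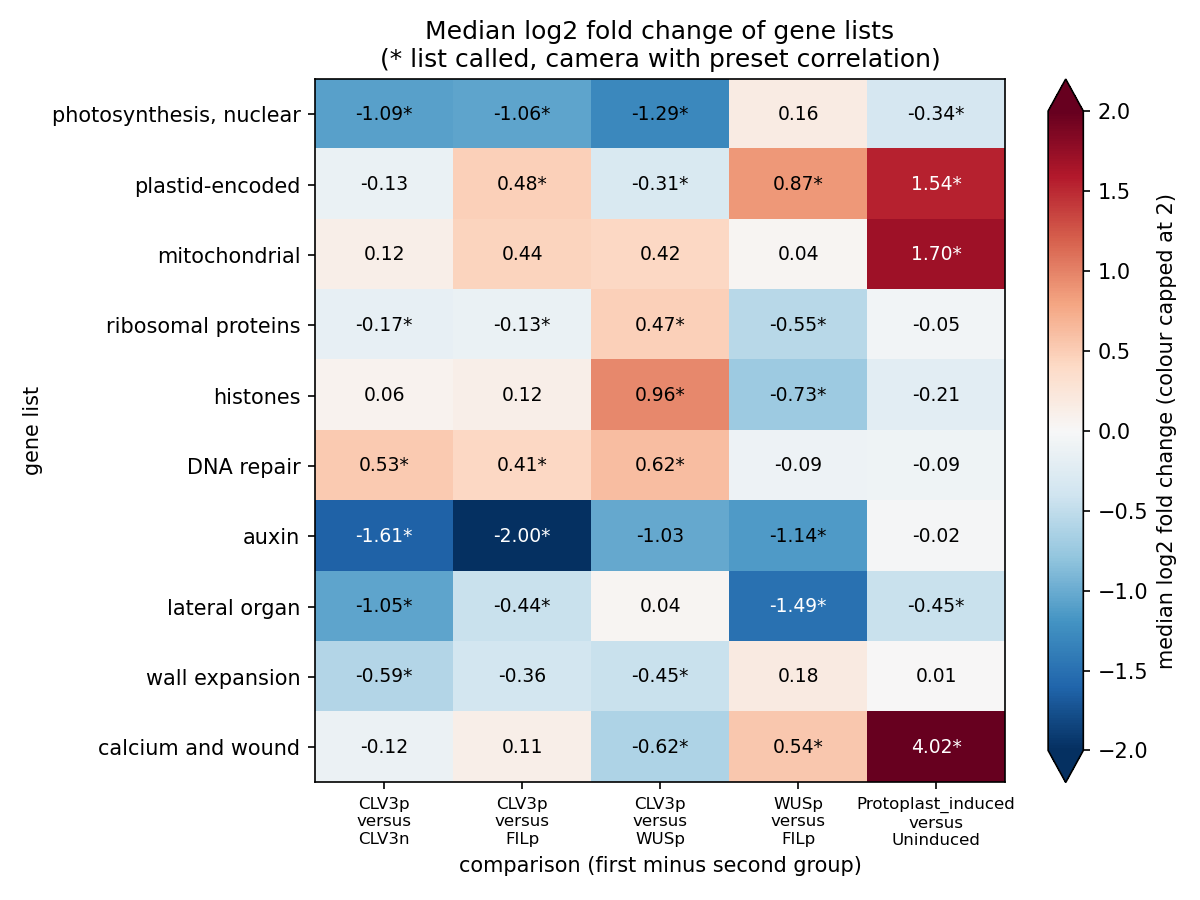
Median log2 fold change of 10 gene lists (vertical axis) in the 5 comparisons (horizontal axis, first minus second group), with colour capped at 2 and a star where camera with the preset correlation called the list. The photosynthesis list has -1.09, -1.06 and -1.29 in the 3 comparisons of CLV3p, and the ribosomal protein list has 0.47 for CLV3p against WUSp and -0.55 for WUSp against FILp; with an estimated correlation no list is called.

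The 3 positive populations were then compared jointly, to find genes higher in 1 than in both others. In CLV3p 658 probe sets were, 252 of them by at least 2-fold against both. Besides CLV3, they include AT1G65810, with a signal of 3039 in CLV3p, 19.6 in FILp and 24.3 in WUSp, AT3G25610 (176, 9.73 and 6.09), AT5G20460 (100.3, 6.33 and 4.998) and AT1G35280 (186, 8.596 and 12.97). In CLV3n these 4 had 779, 9.73, 69.7 and 122, so that AT3G25610 was the one with a low signal in CLV3n too. Floored, their log2 differences over FILp and WUSp were 6.44 and 6.66, 3.03 and 3.18, 2.36 and 2.36, and 3.26 and 3.26. In FILp 479 probe sets were higher than in both others, 326 by at least 2-fold. They include YAB5, AT2G19650 (440 in FILp, 8.07 in CLV3p and 16.1 in WUSp), AT4G10910 (291, 3.86 and 10.8) and AT2G20100 (751, 12.2 and 30.1). Floored, CLV3p and WUSp differed from FILp by -4.50 and -4.50 for AT2G19650, -3.90 and -3.90 for AT4G10910, and -5.27 and -4.64 for AT2G20100. In WUSp 496 probe sets were higher, 268 by at least 2-fold, including MGL (519 in WUSp, 4.32 in CLV3p and 17.9 in FILp), AT1G28400 (82.4, 2.48 and 3.35), AT3G28600 (148, 9.69 and 7.72) and GTR2, which encodes a glucosinolate transporter (680, 45.9 and 32.2). Floored, WUSp differed from FILp by 3.94, 2.08, 2.698 and 4.37 for these 4, and CLV3p from WUSp by -4.73, -2.08, -2.92 and -3.74. In CLV3n AT1G28400 had a signal of 246, above its 82.4 in WUSp, so WUSp was not its highest sorted population. MGL, AT3G28600 and GTR2 had lower signals in CLV3n than in WUSp. The FILp genes named here had lower signals in CLV3n than in FILp.

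These counts compare with 184, 141 and 136 under independence, and with 0.00, 0.02 and 0.02 in simulations without differences. Neither is a fitting reference, since data without differences give almost no calls and the 2 comparisons behind each count share a population. Lists of the same lengths from simulated groups without differences overlapped by 525, 433 and 551. Against these the counts of CLV3p and FILp, 658 and 479, were higher and that of WUSp, 496, was lower. Such lists are ranked by noise alone, so their overlap comes from the noise of the shared population. Calls that hold real differences need not overlap in the same way, so this reference does not decide whether a count is high or low. With the bioC batch as a block the counts were 473, 475 and 420. They depended on WUSp arrays: without WUSp 1 they were 324, 277 and 144, and without WUSp 2 they were 408, 289 and 263, while FILp had 305 without FILp 3. The block ended the calls of MGL, AT3G28600 and AT4G10910 between WUSp and FILp (adjusted p = 0.217, 0.107 and 0.0937). Without WUSp 1 calls ended between CLV3p and WUSp for AT5G20460, AT1G28400 and AT3G28600 (adjusted p = 0.112, 0.07004 and 0.199) and between WUSp and FILp for MGL, AT1G28400, AT3G28600 and AT4G10910 (0.187, 0.1302, 0.219 and 0.0651). Without WUSp 2 they ended between CLV3p and WUSp for AT3G25610 and AT3G28600 (0.052 and 0.252) and between WUSp and FILp for MGL, AT1G28400, AT3G28600 and AT4G10910 (0.0868, 0.073, 0.284 and 0.0855). AT3G28600 also fell short of CLV3p without CLV3p 1 or CLV3p 2 (0.105 and 0.0611) or both CLV3n 1 and CLV3p 1 (0.0963), and of FILp without FILp 1 or FILp 3 (0.111 and 0.114). AT3G25610 fell short of FILp without CLV3p 1 (0.051), and AT4G10910 of WUSp without FILp 2 or FILp 3 (0.0561 and 0.0886).

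The protoplasting pair measured what preparing protoplasts goes with. CML37, which encodes a calmodulin-like protein, had signals of 1482 in Protoplast_induced and 7.49 in Uninduced, a log2 difference of 7.63 ± 0.33 (n = 2 and 2; adjusted p = 5.37e-08; 6.27 floored). AT1G19210, the ubiquitin ligase gene PUB19, CML23, AT3G02840 and the transcription factor gene ORA47 rose by 6.43 ± 0.20, 6.19 ± 0.31 (5.53 floored), 5.92 ± 0.51 (3.61 floored), 5.80 ± 0.22 and 5.25 ± 0.15. In the calcium and wound list 9 of 10 genes rose and none fell (9 and 1 when adjusted over the list alone), with a median of 4.02 (adjusted p = 2.18e-10, and adjusted p = 0.216 with an estimated correlation). All 3 measured genes of the wound, touch and defence list rose, STZ by 4.90 ± 0.52, WRKY53 by 3.70 ± 0.22 and WRKY22 by 1.64 ± 0.21, as did both heat shock genes, ATHSP22.0 (3.29 ± 0.77; 2.17 floored) and AT5G37670 (0.94 ± 0.16). Levels of CML37 were as high in the sorted cells: its mean signal was 1855 in CLV3p, 2549 in CLV3n, 3371 in FILp and 3587 in WUSp. The difference of CLV3 was 0.39 ± 0.26 (adjusted p = 0.316).

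Organelle transcripts rose together. Of 62 plastid-encoded transcripts 58 were higher in Protoplast_induced and none lower, with a median of 1.54 (adjusted p = 9.53e-44, and adjusted p = 0.288 with an estimated correlation), petL at 2.88 ± 0.34. All 15 mitochondrial transcripts were higher, with a median of 1.70 (adjusted p = 1.06e-14, and adjusted p = 0.305 with an estimated correlation), nad6 at 3.36 ± 0.20 and cox1 at 2.47 ± 0.11. The poly-A spike controls were also higher in Protoplast_induced, with mean log2 signals of 11.30 and 8.37, and the actin 3'/5' ratio was 3.40 against 2.59. Nuclear photosynthesis genes had 4 of 9 lower, with a median of -0.34 and LHCB4.1 at -0.81 ± 0.15 (list adjusted p = 0.0121, and adjusted p = 0.542 with an estimated correlation). Among the genes for chloroplast proteins 7 of 27 were lower, with a median of -0.20 and PSBY at -1.34 ± 0.13 (list adjusted p = 0.0177, and adjusted p = 0.361 with an estimated correlation). Lateral organ genes had 3 of 13 lower and a median of -0.45, with ROXY1 at -0.91 ± 0.14 (list adjusted p = 0.0127, and adjusted p = 0.489 with an estimated correlation), and flavonoid genes had 4 of 6 lower and a median of -0.57, with UF3GT at -0.88 ± 0.17 (list adjusted p = 0.00283, and adjusted p = 0.288 with an estimated correlation). PRL, a DNA replication gene, fell by 0.68 ± 0.11 and the ligase gene ATLIG4 rose by 0.69 ± 0.14, while neither was called in a sorted comparison. Expansin and xyloglucan endotransglucosylase genes had 1 of 10 higher and 3 lower (adjusted p = 0.746), XTH19 at 1.09 ± 0.30 and EXPB3 at -1.07 ± 0.12. Genes chosen by measured fold as lower include AT1G31710 (-1.75 ± 0.46), AT5G59170 (-1.68 ± 0.32) and AT3G09030 (-1.60 ± 0.30).

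Of 13911 probe sets 3052 differed, 1463 higher and 1589 lower, and by at least 2-fold 516 and 153. With each array centred on its median 3080 differed, and the share higher was 34.1% in place of 47.9%. The count was 1738 without Protoplast_induced 1 and 727 in a fit of all 15 arrays. Without Protoplast_induced 1 and without Protoplast_induced 2, 1 and 1 of the 4 nuclear photosynthesis genes and 3 and 4 of the 7 genes for chloroplast proteins were still lower, and the lateral organ list was not called without Protoplast_induced 2 (adjusted p = 0.0513). AT1G31710 lost its call without Uninduced 2 (adjusted p = 0.12) and petL without Uninduced 1 or Uninduced 2 (0.0973 and 0.118), and XTH19 without Protoplast_induced 1, Protoplast_induced 2 or Uninduced 2 (0.0851, 0.1305 and 0.0717).

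Genes that moved with protoplasting were set against the cell type calls. Of the 986 probe sets higher in WUSp than in FILp, 289 had also risen with protoplasting, where 101 were expected, an odds ratio of 4.35 (95% interval 3.73 to 5.07; Fisher's exact test, adjusted p = 5.44e-68). With the bioC batch block the odds ratio was 2.51 (2.07 to 3.02). Of those higher in FILp, 256 had fallen, with 127 expected (odds ratio 2.58). Among probe sets higher in CLV3p than in FILp 243 had risen (148 expected, 1.94), and among those higher in FILp 363 had fallen (203 expected, 2.30). Against WUSp, 281 of those lower in CLV3p had risen (179 expected, 1.85). For CLV3p and CLV3n the largest ratio was for genes higher in CLV3n, of which 271 had fallen (148 expected, 2.28). In 14 of the 16 pairs the overlap differed from independence after adjustment, and probe sets are not independent replicates. Without the probe sets called in protoplasting, 12083 were tested in place of 15052, which by itself lowers the counts. Of these, 1546, 2613, 2821 and 1603 differed between CLV3p and CLV3n, CLV3p and FILp, CLV3p and WUSp, and WUSp and FILp.

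**Figure D3:**
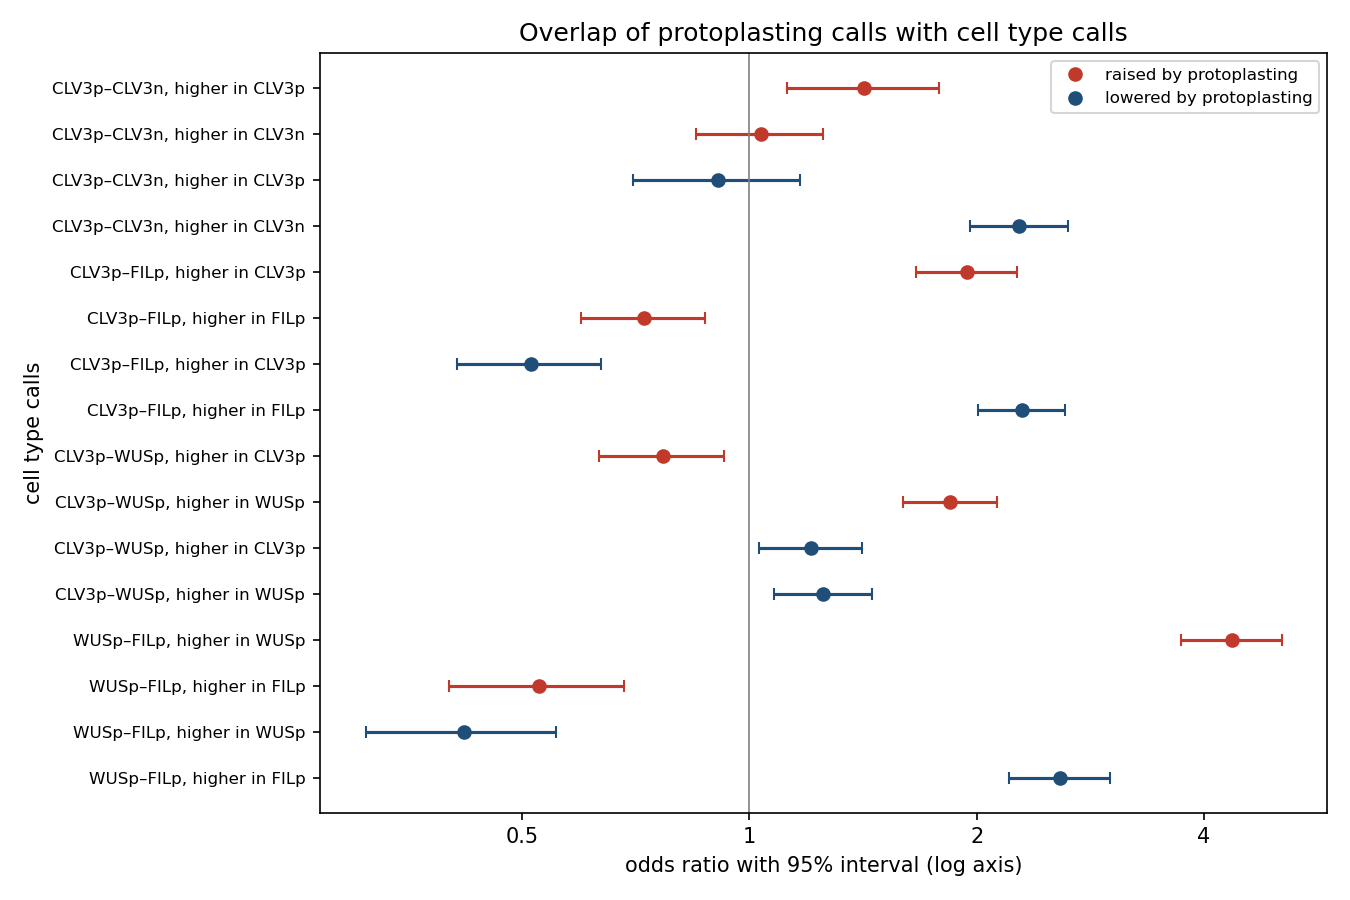
Odds ratios with 95% intervals (horizontal log axis) for the overlap of genes raised (red) or lowered (blue) by protoplasting with the cell type calls (vertical axis, 2 directions in each of 4 comparisons of sorted cells). The highest is 4.35, for genes raised by protoplasting and higher in WUSp than in FILp.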

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

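The tests of exposure of CLV3p cells against FILp and WUSp cells, of mature green cells, of organelle transcripts in protoplasts and of exposure of the WUSp cells, with and without the bioC batch as a block, were chosen after the results they measure were seen. The intervals given below for medians come from resampling the probe sets, with the arrays held fixed. They treat genes as independent and hold none of the spread between arrays, so they do not show how a median would vary in other samples. The poly-A spike controls, which are added during labelling and entered no comparison, were higher in Protoplast_induced than in Uninduced by 2.93 on the log2 scale, with means of 11.30 ± 0.44 and 8.37 ± 0.13 (SD, n = 2 each). The 25S ribosomal RNA control, also outside the comparisons, was higher on the 11 arrays of sorted cells than in Uninduced by 1.71 on the log2 scale, with means of 14.65 ± 0.31 and 12.94 ± 0.18 (SD).

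Nuclear photosynthesis genes were lower in CLV3p than in CLV3n, FILp and WUSp. Stronger exposure of the CLV3p cells to protoplasting, as the whole cause, would lower the 1577 other probe sets that protoplasting lowers by a median beyond -0.5, but their median difference was -0.0559 (-0.0782 to -0.0295) against CLV3n, -0.165 (-0.192 to -0.135) against FILp and -0.0345 (-0.0605 to 0.0101) against WUSp. Exposure as a part of the cause is not excluded, since genes lowered by protoplasting were over-represented among those lower in CLV3p than in CLV3n and FILp (odds ratios 2.28 and 2.30). Genes raised by it were over-represented among those higher in CLV3p than in CLV3n and FILp (1.42 and 1.94). The calcium and wound list, which protoplasting raised by a median of 4.02, went less that way. Its median difference was -0.12 against CLV3n, 0.11 against FILp and -0.62 against WUSp. Against WUSp the overlap was weaker and went both ways, with odds ratios of 1.25 among genes lower and 1.21 among genes higher in CLV3p. Poor RNA on CLV3n 1 and CLV3p 1 was tested against CLV3n alone, with a smaller difference predicted without these arrays. The median of the list was then -1.002 (-1.65 to -0.71), so the difference does not rest on these arrays alone. Each group holds 1 of them, so an effect shared by both would cancel, and the fit cannot decide on RNA quality. RNA of mature green cells in the other populations remains open: the lowest of the 3 medians of the plastid-encoded transcripts was -0.31 (-0.46 to -0.14, against WUSp), but protoplasting moves that list itself, and a lower level of these genes in the CLV3p cell type is untested and may equally hold.

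Plastid and mitochondrial transcripts were higher in Protoplast_induced than in Uninduced. With each array centred on its median the plastid median was 1.46 (1.28 to 1.63). Centring moved all probe sets of the comparison by the same -0.083, so a common shift between the arrays is too small to account for the rise. A scaling effect that differs between probe sets is not tested by it. More labelling of RNA without a poly(A) tail would raise the 25S ribosomal RNA control as well, and its largest difference among the 4 pairs of arrays was 0.14. Less plant RNA beside the poly-A spikes cannot be told apart from the groups, since the smallest of the 4 spike differences was 2.53 and every array of a group shares it. A response of organelle transcripts to protoplasting is untested and may also account for the rise.

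Genes raised by protoplasting were over-represented among those higher in WUSp than in FILp. The batch read from bioC, as the whole cause, is argued against by an odds ratio of 2.51 (2.07 to 3.02) when blocked. This is lower than 4.35 without the block. Organelle transcripts are argued against by an odds ratio of 4.42 (3.78 to 5.16) without them. Stronger exposure of the WUSp cells to protoplasting remains open: the 395 nuclear genes raised at least 2-fold by protoplasting had a median difference between WUSp and FILp of 0.66 (0.54 to 0.77), but 0.20 (0.10 to 0.35) with the bioC batch as a block. With that block the calcium and wound list, which protoplasting raised by a median of 4.02, had a median of -0.18 (adjusted p = 0.961). The first median repeats the pattern in other terms, and higher levels of the same genes in the WUSp cell type are untested and would give the same value.

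Other splits of the 6 arrays of CLV3p and CLV3n gave at most 6 calls, against 2082 for the real one, and other splits of the 6 arrays of CLV3p and FILp gave 0, against 3407. The real split alone (1 of 10) gave as many in both cases, and 10 splits are too few for a share under 0.05.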

How the results depend on the processing

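The fits by bioC batch, the fit without CLV3n 1 and CLV3p 1, the centred list tests and the list tests that left out an array were chosen after seeing the data. The 8 counts stayed within 1.5 times their reported values except as follows, and the cause was not tested. Array weights gave 3587 calls for WUSp against FILp and 778 probe sets higher in WUSp. Protoplasting had 1972 calls with plain eBayes and 727 in a fit of all 15 arrays, in which it takes the spread of the sorted cells, and CLV3p against CLV3n had 1134 and 1184 in the high and low bioC batch, with fewer arrays. Leaving out 1 array gave 1471 to 2193 calls for CLV3p against CLV3n, 2455 to 3189 against FILp, 1630 to 3549 against WUSp, 980 to 1889 for WUSp against FILp and 1738 to 3336 for protoplasting, and 324 to 647, 277 to 483 and 144 to 506 probe sets higher in CLV3p, FILp and WUSp. Where 1 array of a group was left, it was assumed to vary like the other groups. List calls numbered 50, and 0 with an estimated correlation, 47 with quantile normalization and 42 with the bioC batch block (40 of them among the 50). Under the block the calcium and wound list of WUSp against FILp turned (camera adjusted p = 0.961). The arrays of the protoplasting pair are all in the high bioC batch, so the block could not change their fit, and their list calls do not test it. In the fits that left out 1 array, 38 of the 50 list calls held every time and 12 ended at least once. With quantile normalization 14 overlaps passed too, but genes raised by protoplasting and higher in CLV3p than in CLV3n no longer did (odds ratio 1.21, adjusted p = 0.133) and 1 other pair newly did. Equal replicate numbers were not taken as pairs, and whether they are is open. CLV3p and CLV3n arrays with the same number correlated at 0.32, 0.04 and 0.32 after group means were removed. That is a hint in that each correlated best with its own number, but the second lies under the 0.1 asked of every pair. Another hint is the GAPDH 3'/5' ratio. On arrays 1, 2 and 3 its log2 was 1.42, 1.13 and 0.58 in CLV3p and 1.37, 0.99 and 0.56 in CLV3n. The actin ratio and the 25S control also kept the same order in both groups, while the ubiquitin ratio did not. The replicate block spans every array of its fit, so CLV3p and CLV3n alone were not compared as pairs. With the replicate number as a block the counts were 2283, 3600, 3619, 2226 and 3654 for the 5 comparisons, 674, 500 and 487 for the populations, and 46 list calls passed, 45 of them among the 50. Among the calls that ended were those of the calcium and wound list for CLV3p against WUSp and WUSp against FILp (camera adjusted p = 0.128 and 0.0665). Of all 494 gene values chosen by the rule fixed in advance, 314 kept direction and call in every fit that left out 1 array and 180 kept direction only. With the bioC batch block 88 of 88 called genes kept their call for CLV3p against CLV3n, 110 of 124 against FILp, 104 of 106 against WUSp and 62 of 89 for WUSp against FILp. Low signal over background limits genes whose arrays lie under the floor, and the measured fold by which they were chosen does not rank their changes against other genes.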

Other observations

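Gene families outside the themes above also differed, and their lists were written before any fold change was computed. The CYP71B family of cytochromes P450 had 6 of 8 measured members lower in CLV3p than in CLV3n, with a median of -2.29 (adjusted p = 9.87e-05, and adjusted p = 0.216 with an estimated correlation), and 6 lower than in FILp, with a median of -2.78 (adjusted p = 6.05e-05, and adjusted p = 0.216 with an estimated correlation). Between WUSp and FILp 3 were lower in WUSp, with a median of -1.12 (adjusted p = 0.00203, and adjusted p = 0.216 with an estimated correlation). CYP71B23 had signals of 2.68 in CLV3p and 106 in CLV3n (-5.30 ± 0.77; -2.44 floored) while against FILp CYP71B23 had -6.05 ± 0.77 (-3.19 floored) and CYP71B22 had -4.28 ± 0.39 (-4.14 floored). Of 5 GSTU glutathione transferase genes, 2 were lower in CLV3p than in CLV3n, 3 than in FILp and 3 than in WUSp (adjusted p = 0.0389, 0.0113 and 0.00951, and adjusted p = 0.489, 0.361 and 0.356 with an estimated correlation). GSTU20 was lower in each, at -5.22 ± 0.52 (-3.76 floored), -4.21 ± 0.52 (-2.76 floored) and -3.77 ± 0.58 (-2.32 floored). GSTU16 had -3.91 ± 0.98 (-2.51 floored) against WUSp, a call that ended without WUSp 1 or WUSp 2 (adjusted p = 0.102 and 0.0618). The GSTU call against CLV3n ended with quantile normalization (adjusted p = 0.109) and without CLV3n 1, CLV3n 2 or CLV3p 3 (0.158, 0.0552 and 0.0871), and the list's median was -1.57 within the high and 0.13 within the low bioC batch. The sugar transporter family SWEET and the TBL family, with 3 of 6 (4, and 1 higher, when adjusted over the list alone) and 3 of 14 lower in CLV3p than in CLV3n, were led by SWEET10 (-2.90 ± 0.58) and TBL38 (-2.68 ± 0.44), with list adjusted p of 0.049 and 0.014 (adjusted p = 0.233 and 0.216 with an estimated correlation). The SWEET call ended with quantile normalization (adjusted p = 0.0871) and with the bioC batch block (adjusted p = 0.0654). It also ended without CLV3n 1, CLV3n 2, CLV3p 1, CLV3p 2 or CLV3p 3 (0.126, 0.0552, 0.0612, 0.0585 and 0.104), and 1 of the 3 genes was still lower without CLV3n 1.

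Of 25 UGT glycosyltransferase genes, 10 were higher and 2 lower in WUSp than in FILp, with a median of 0.89 (adjusted p = 0.000758, and adjusted p = 0.216 with an estimated correlation), and 7 were lower and 2 higher in CLV3p than in WUSp (adjusted p = 0.0168, and adjusted p = 0.302 with an estimated correlation). Both calls ended with the bioC batch block (adjusted p = 0.0683 and 0.0545), with medians of 0.64 and -0.41. Without WUSp 1, 6 of the 10 genes were still higher in WUSp than in FILp, and 4 of the 7 lower in CLV3p than in WUSp. UGT84A3 was lower in CLV3p than in WUSp at -3.62 ± 0.40, while the flavonol rhamnosyltransferase gene UGT78D1 went the other way, at 3.60 ± 0.36, and was lower in WUSp than in FILp at -3.54 ± 0.36. Of 8 BGLU glucosidase genes, 4 were lower in CLV3p than in WUSp, with a median of -0.93 (adjusted p = 0.00164, and adjusted p = 0.231 with an estimated correlation), and 4 were higher in WUSp than in FILp (6, and 1 lower, when adjusted over the list alone), with a median of 1.203 (adjusted p = 0.00164, and adjusted p = 0.231 with an estimated correlation), the latter 0.80 with the bioC batch block (adjusted p = 0.0716). Without WUSp 1 or WUSp 2 each of these counts of 4 was 2. BGLU46 had signals of 94.3 in CLV3p, 106 in FILp and 1067 in WUSp, and BGLU44 was lower in CLV3p than in WUSp at -3.35 ± 0.43. The families SCPL, TET and TRM and the added lists for mitosis and meiosis were called in no comparison, with smallest adjusted p of 0.376, 0.314, 0.176, 0.134 and 0.864. The receptor kinase gene EMS1 of the meiosis list was lower in CLV3p than in CLV3n and FILp (-1.70 ± 0.18 and -2.12 ± 0.18).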
